A study of Danio rerio with 12 samples.

How the data were processed

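Total RNA of zebrafish hearts was isolated with Trizol and sequenced on the Illumina HiSeq by the authors, 3 libraries at each of 4 ages (6, 12, 24 and 36 months). Per the submitters' processing notes, base calling used CASAVA 1.8 and reads were aligned with HISAT2 2.0.5 to the GRCz11 build. The deposited values are FPKM, 1 column per library, in 4 tables of 50640 genes with identical annotation, of which 35116 have an Ensembl identifier and 15524 are loci without a name. The tool that counted reads, the annotation release and the way loci without a name were assembled are not stated.

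The scale of the values was checked on the files. FPKM times gene length came out as whole reads for 100% of the values of each library within 0.01 read, which gave 7333060 to 11145869 reads in genes per library. For a gene of 1 kilobase, 1 read is a step of 0.0878 to 0.136 FPKM. The library size implied by the steps followed median-ratio size factors over all 12 libraries to 0.988% of its mean (highest minus lowest), so the 4 tables share 1 scale and were used as deposited. Replicate numbers were tested for pairing: over 18 pairs of libraries of different ages with the same number, the correlation of deviations from the age means across genes ran from -0.154 to 0.106, with 1 pair over 0.1. No pairing by number was seen, so the samples were treated as unpaired. This check cannot show that the numbers share no preparation or order.

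The comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes with a mean FPKM of at least 1 over the 12 libraries were tested, 16223 in all, on log2(FPKM + 1). A model with 4 age means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), giving 8 residual degrees of freedom. The pairwise comparisons, an F test across the ages and a linear trend in months were each adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All tests are two-sided. Noncoding genes are those of the biotypes lincRNA, antisense RNA, processed transcript, sense intronic and sense overlapping, and their counts use the same adjusted p. Other RNA classes, such as rRNA, snRNA, snoRNA and miRNA, are not among them.

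Lists of genes for heart muscle, other cell types, metabolism, signalling, stress and ageing, 43 in all, were written from general knowledge of the tissue. They held 2769 symbols, of which 2537 matched a table name, 97 a synonym and 135 nothing, giving 2631 genes. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 43 lists of a comparison. Of the lists called by camera with the preset correlation (11 for 36 against 6 months, 6 for 24 against 6, 4 for 12 against 6, 5 for 24 against 12 and 11 for 36 against 24), 0 held with an estimated correlation.

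Genes were named by rule. Among genes past the threshold whose values did not overlap between both ages and whose symbol is not a clone or placeholder name, the 10 largest rises and 10 largest falls in log2(FPKM + 1) were named for 36 against 6 months, and 5 and 5 for each other pairwise comparison. For the trend, the 5 steepest each way were named without the overlap condition. The 3 largest rises and falls of noncoding genes were named whatever their name, and for each list described up to 4 members with the smallest p. A gene on the same strand as an overlapping locus without a name is described as uncertain, since reads in the overlap can be given to either or to neither.

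The procedure was tested for 36 against 6 months on simulated data with the gene means and residual spreads of the real libraries. Of 200 simulated changed genes, 45% of those with a 2-fold and 79% of those with a 4-fold change were called, and 7 calls (5.34%) were of genes that had not been changed. A single shifted list was called by camera with both correlations and by fry, and 0 other lists were. Each gene was drawn independently of the others. The simulation therefore cannot show how the list tests behave where genes of a list vary together.

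The alternatives were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, median-ratio size factors, quantile normalization, an equal sum per library, the removal of mitochondrial and haemoglobin genes, replicate number as a block, only the 2 ages compared, eBayes without trend, limma voom on the recovered reads, log2 of age, a required doubling or halving, and leaving out each library in turn. Alternatives added after the data were seen were loci without a name left out, those loci and the genes they overlap left out, and array weights. Further tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sex, strain, pooling and collection time are not given and were not modelled.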

Results

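Gene expression was measured by sequencing of total RNA from zebrafish (Danio rerio) hearts at 4 ages, 6, 12, 24 and 36 months, with 3 libraries per age and 12 in all. The series follows the natural ageing of the heart. Each library is given as FPKM (fragments per kilobase of gene, divided by a size that follows median-ratio size factors rather than the reads in genes). The values cover 50640 genes of the GRCz11 build, of which 15524 are loci without a name. The reads in genes ranged from 7333060 (36 months, replicate 1) to 11145869 (12 months, replicate 3), and 28378 to 30160 genes had reads in a library. With a mean FPKM of at least 1, 16223 genes entered the tests, of which 9926 are protein-coding, 362 noncoding and 5730 loci without a name. Levels below are FPKM as mean ± SD over the 3 libraries of an age. Log2 differences are of FPKM + 1, with their standard error, so they understate the change of genes with low levels. The labels do not say whether replicates were separate animals or pools, nor their sex, so p-values measure only the spread between these samples.

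Apart from replicate 1 of 6 months, age ordered the libraries along the first principal component, which held 21.9% of the variance (PC2 held 14.5%). The 3 libraries of 36 months lay at 40.1 to 51.8 on PC1, and replicates 2 and 3 of 6 months lay at the other end, at -40.8 and -34.7. Between them lay 12 months at -20.4 to -14.1 and 24 months at -5.3 to 6.3. Replicate 1 of 6 months stood apart from the other 6-month libraries at -4.07, among those of 24 months, and took the highest value of all libraries on PC4 (55.6). Its gapdh level, a glycolytic enzyme, was 6766 FPKM against 21920 and 21520 in the other 6-month libraries, and its ckma level, the muscle creatine kinase, was 970 against 4762 and 4080. The gapdh level was also lower at 24 months (8975 to 13510) than at 12 months (17940 to 22600). Mitochondrially encoded genes took 3.88% to 5.67% of the reads and haemoglobin genes 0.088% to 0.446%.

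**Figure D1:**
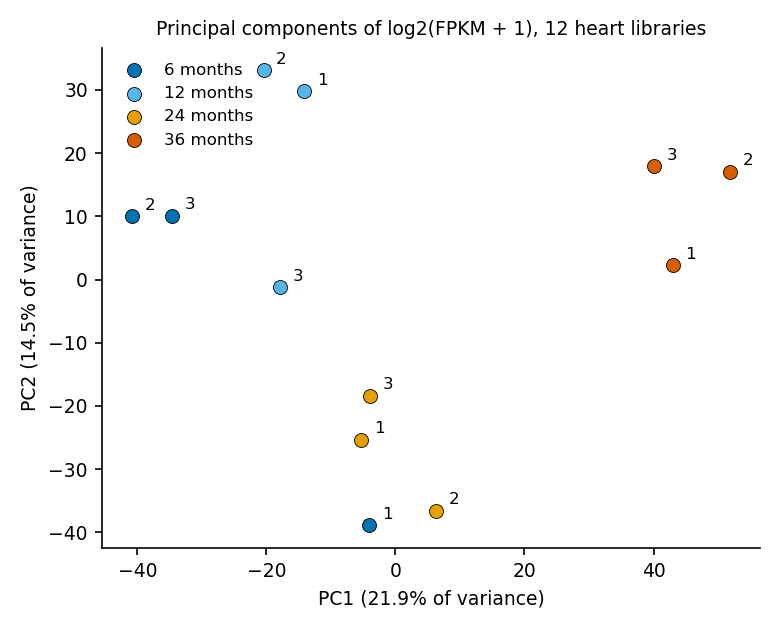
Principal components of the 12 heart libraries. Each point is a library, coloured by age and numbered by replicate, on PC1 (21.9% of the variance) and PC2 (14.5%) of log2(FPKM + 1) over the genes tested; the 36-month libraries lie at 40.1 to 51.8 on PC1.

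The oldest hearts were first compared with the youngest. Several genes of the immediate early response, which cells switch on within minutes of a stimulus, were lower at 36 than at 6 months. The AP-1 component fosab fell from 70.4 ± 23.4 to 7.53 ± 2.41 FPKM (log2 -3.04 ± 0.43, adjusted p = 0.00484), and atf3, a stress-induced transcription factor, from 292 ± 63.1 to 56.5 ± 11.8 (log2 -2.35 ± 0.24, adjusted p = 0.00104). The zinc finger factor egr1 fell from 80.9 ± 21.6 to 12.4 ± 3.0 FPKM, the orphan nuclear receptor nr4a1 from 216 ± 98.2 to 29.8 ± 3.21, and jun from 331 ± 51.7 to 119 ± 14.4. The antiproliferative gene btg2 fell by 2.72 ± 0.38 on the log2 scale, but a locus without a name overlaps it on the same strand, so its level is uncertain. Outside that list, otud1, a deubiquitinase, fell from 179 ± 50.9 to 30.8 ± 0.253 FPKM, and nr1d1, a repressor of the circadian clock, from 67.1 ± 23.4 to 11.58 ± 1.7. SYCE3, a synaptonemal complex gene, fell by 2.16 ± 0.40 on the log2 scale, and ppp1r27b, a subunit of protein phosphatase, by 2.43 ± 0.59. Of the 42 immediate early genes tested, 13 were lower, 1 higher and 28 did not pass. Adjusted over the list alone, 15 were lower and 2 higher. The list stood below other genes by camera (adjusted p = 3.45e-06; adjusted p = 0.978 with an estimated correlation), and fry, which asks whether its genes moved on balance in a single direction, gave adjusted p = 0.0251.

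**Figure D2:**
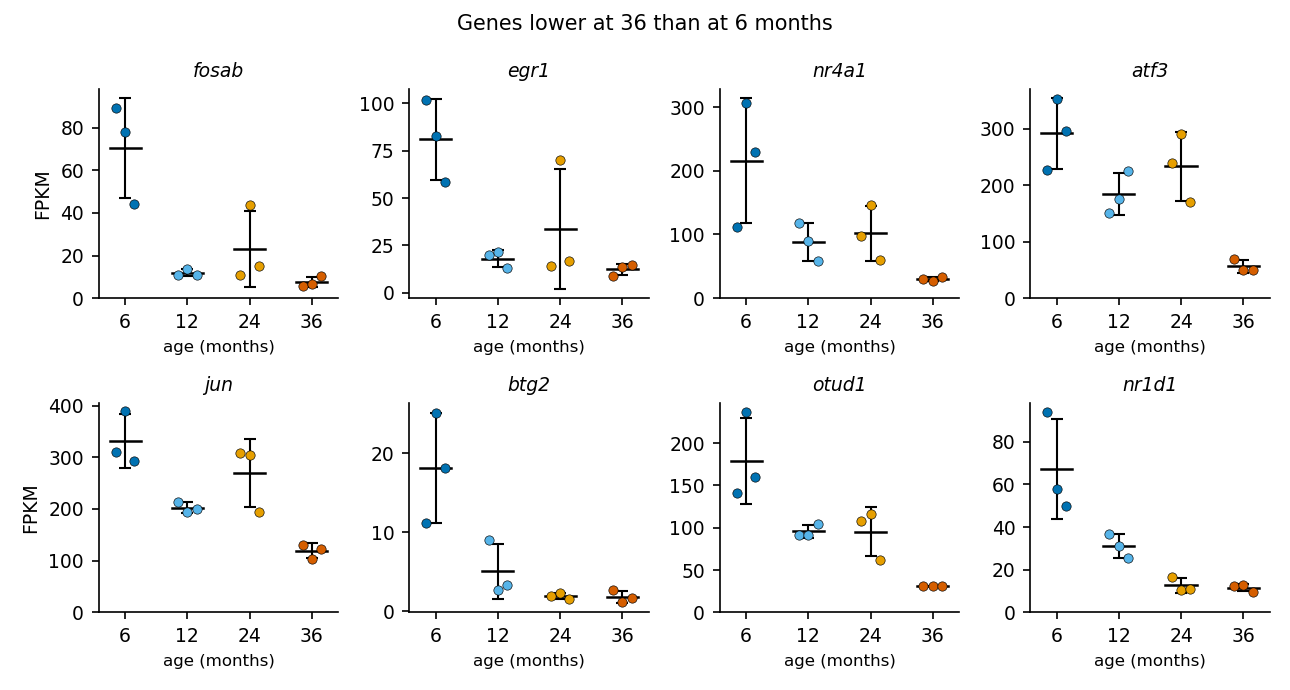
Levels of 8 genes that were lower at 36 than at 6 months. Points are FPKM of single libraries by age in months, horizontal lines are means and bars are SD over 3 libraries; fosab went from 70.4 ± 23.4 to 7.53 ± 2.41 and atf3 from 292 ± 63.1 to 56.5 ± 11.8. A locus without a name overlaps btg2 on the same strand.

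In the same comparison the named genes that rose with the smallest p-values were srebf2, given below, and foxo1a (ENSDARG00000099555; chromosome 15, 3296910 to 3391535, plus strand), a forkhead transcription factor restrained by insulin signalling. The level of foxo1a rose from 8.99 ± 3.3 to 64.7 ± 11.2 FPKM (log2 2.75 ± 0.25, adjusted p = 0.000655), with 19.1 ± 5.47 at 12 and 14.4 ± 2.61 at 24 months. The zinc finger factor zbtb16b rose from 1.91 ± 0.985 to 24.1 ± 1.94 (log2 3.16 ± 0.35, adjusted p = 0.00167). The low-density lipoprotein receptor gene ldlrb went from 0.924 ± 0.673 to 10.8 ± 3.37 FPKM, insig1, which holds back sterol synthesis, from 5.18 ± 1.26 to 18.1 ± 3.84, and angptl4, an inhibitor of lipoprotein lipase, from 21.9 ± 20.1 to 113 ± 34.4. The sterol regulator srebf2 rose by 1.61 ± 0.15 on the log2 scale (adjusted p = 0.000655), although a locus without a name overlaps it on the same strand and makes its level uncertain, and the sterol isomerase ebp rose by 1.21 ± 0.23. Of 38 genes of cholesterol and fatty acid synthesis tested, 7 were higher, 1 lower and 30 did not pass. Adjusted over the list alone, 8 were higher and 1 lower. Camera called the list (adjusted p = 0.0017), and adjusted p = 0.978 with an estimated correlation did not. Of 59 genes of insulin, TOR and sirtuin signalling, 2 were higher and 0 lower, over all genes and adjusted over the list alone. The 2 were foxo1a and irs4a, an insulin receptor substrate (log2 0.84 ± 0.14). Camera did not call that list (adjusted p = 0.634; adjusted p = 0.978 with an estimated correlation). Immune genes among the largest rises were the chemokines ccl38a.4 (log2 3.25 ± 0.79) and CXCL11 (1 of many) (log2 2.95 ± 0.75), and cst14b.2, a cystatin, rose by 2.64 ± 0.57. The immunoglobulin light chain segment igl3v3 was listed at 0 in all 3 libraries of 6 months and at 11.8 ± 5.66 FPKM at 36 months, overlapped by a locus without a name. The remaining genes with the largest changes were copies of multi-copy RNAs, snoMBII-202 (log2 3.34 ± 0.61) and a pair of 5S_rRNA genes (log2 2.63 ± 0.61 and -2.29 ± 0.45), whose reads cannot be placed with certainty.

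**Figure D3:**
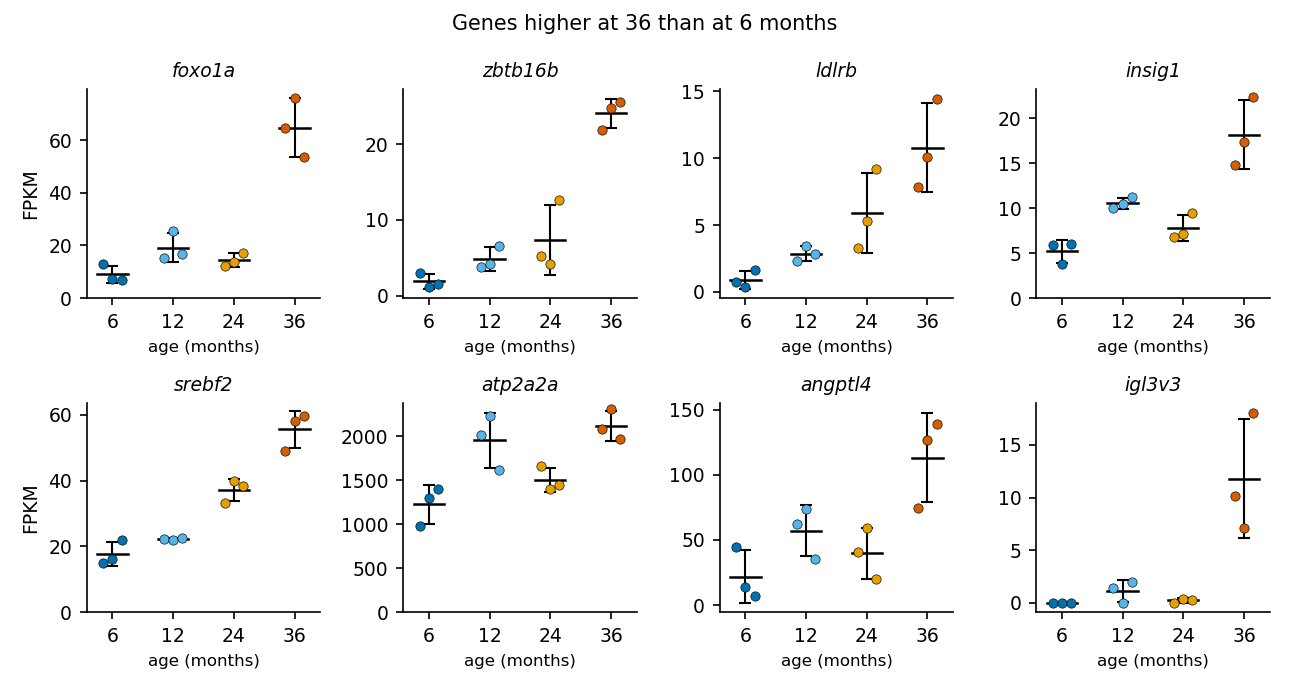
Levels of 8 genes that were higher at 36 than at 6 months. Points are FPKM of single libraries by age in months, horizontal lines are means and bars are SD over 3 libraries; foxo1a went from 8.99 ± 3.3 to 64.7 ± 11.2 and ldlrb from 0.924 ± 0.673 to 10.8 ± 3.37. Loci without a name overlap srebf2 and igl3v3 on the same strand.

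Between 6 and 36 months, 1338 of the 16223 genes tested (8.2%) passed an adjusted p of 0.05, 641 higher and 697 lower, and 595 of them at least doubled or halved FPKM + 1. Counts of list members stand against that 8.2%. The balance depends on the processing, with 491 higher and 398 lower with no filter. Fewer genes passed in a fit of only the 2 ages compared, as given below. The 10 largest named rises and 10 largest named falls kept their call in each of 4 rescalings of the libraries, as did 51 of 68 members of lists. The rescalings were small, moving the median of all genes by at most 0.0853 on the log2 scale. Median-ratio size factors, among the 4, nearly repeat the deposited scale. Among list members given below, pcxa, serpinh1b, mmp9, tp53i11b, fkbp4, psma1 and sox7 lost it with mitochondrial and haemoglobin genes removed (adjusted p = 0.0533, 0.0549, 0.051, 0.0563, 0.0558, 0.051 and 0.0531). Without at least 1 library 7 of the 20 largest named changes lost their call: ccl38a.4, CXCL11 (1 of many), angptl4, cst14b.2, ppp1r27b and both 5S_rRNA genes. Their adjusted p then reached 0.101, 0.117, 0.0713, 0.0728, 0.102, 0.0877 and 0.0547 in that order. The libraries were replicates 2 and 3 of 6 months and all 3 of 36 months, and for CXCL11 (1 of many) also the 3 of 24 months. The count was 2088 without replicate 1 of 6 months, 608 and 591 without replicates 2 and 3 of 6 months, and 612, 479 and 670 without replicates 1, 2 and 3 of 36 months.

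Among genes of the heart muscle, the cardiac transcription factor nkx2.5 fell from 161 ± 6.75 to 97.8 ± 11.12 FPKM between 6 and 36 months (log2 -0.72 ± 0.11, adjusted p = 0.00619), and hey2, a Notch target of ventricular and endocardial cells, rose from 7.88 ± 1.65 to 18 ± 2.79 (log2 1.1 ± 0.18, adjusted p = 0.00852). These were the 2 called among the 8 tested of 25 cardiac transcription factors in the list. Adjusted over the list alone, 1 was higher and 2 lower. Of 39 calcium handling and conduction genes in the list, only 11 were tested, and none of the 22 overlapped on the same strand by a locus without a name. Of the 11 tested, 2 were higher and 1 lower, over all genes and adjusted over the list alone. The calcium pump genes atp2a2a and atp2a2b rose by 0.80 ± 0.17 and 0.58 ± 0.15 on the log2 scale, and the connexin gene cx36.7 fell by 0.99 ± 0.26. By limma, 0 of the 18 sarcomere genes tested passed, over all genes or adjusted over the list alone, and 0 higher and 2 lower had an unadjusted p under 0.05. The ventricular myosin vmhc and the thin filament genes tnnt2a and tnnc1a were listed between 0 and 0.905 FPKM in all libraries. Loci without a name overlap them on the same strand, and only 18 of 35 sarcomere genes were tested. Camera called none of these lists (adjusted p = 0.971, 0.879 and 0.634; adjusted p = 0.985, 0.978 and 0.978 with an estimated correlation). The call of atp2a2a ended without replicate 1 or 2 of 36 months (adjusted p up to 0.0684), and those of atp2a2b and cx36.7 without any library of 36 months or replicate 2 or 3 of 6 months, among others (up to 0.103 and 0.139).

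The mitochondrial enzyme gene ogdhb, of the tricarboxylic acid cycle, rose from 10.44 ± 1.85 to 21.9 ± 3.85 FPKM between 6 and 36 months, and pdhx and pcxa rose by 1.40 ± 0.24 and 0.53 ± 0.13 on the log2 scale, both overlapped by loci without a name. Of 23 genes of that cycle and pyruvate dehydrogenase tested, 3 were higher and 0 lower, and adjusted over the list alone 4 and 1. The fatty acid transporter slc27a1a fell from 47.6 ± 1.77 to 32.1 ± 1.06 FPKM (log2 -0.55 ± 0.10, adjusted p = 0.012). It was the 1 gene called among 24 of fatty acid oxidation, over all genes and adjusted over the list alone. The median of the list was -0.47 on the log2 scale, and -0.65 to -0.30 without single libraries. Camera called fatty acid oxidation lower (adjusted p = 0.0062; adjusted p = 0.978 with an estimated correlation), but not without replicate 2 or 3 of 6 months or replicate 1 of 36 months (adjusted p up to 0.0673). It did not call the tricarboxylic acid cycle (adjusted p = 0.882; adjusted p = 0.985 with an estimated correlation). Without replicate 2 or 3 of 6 months or any replicate of 36 months pcxa lost its call (adjusted p up to 0.0995).

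The matrix and the vessel wall also held changed genes at 36 against 6 months. The metalloproteinase inhibitor timp2b rose from 5.82 ± 4.17 to 25.8 ± 3.97 FPKM (log2 2.13 ± 0.34, adjusted p = 0.00742). Its relative timp4.2 rose from 4.0 ± 2.12 to 11.52 ± 3.98 and the microfibril gene fbn1 from 28.9 ± 1.54 to 42.1 ± 4.17, whereas the collagen chaperone serpinh1b fell by 1.77 ± 0.44 on the log2 scale. Of 49 matrix genes tested, 4 were higher and 1 lower; adjusted over the list alone, 4 and 2. The pericyte gene rgs5a fell from 410.4 ± 106 to 157 ± 20.7 FPKM and lmod1b, a leiomodin of smooth muscle, from 22.4 ± 1.47 to 14.3 ± 0.777. The mural receptor gene PDGFRB and the potassium channel gene kcnj8 rose by 1.02 ± 0.19 and 0.81 ± 0.20 on the log2 scale. Of 31 epicardial, fibroblast and mural markers, 3 were higher and 2 lower, over all genes and adjusted over the list alone. The lymphatic marker lyve1a rose from 10.8 ± 4.91 to 37.07 ± 6.27, the endothelial transcription factor sox7 by 0.66 ± 0.15 and the growth factor receptor kdr by 0.53 ± 0.13 on the log2 scale. Of 42 endothelial and endocardial markers, 5 were higher and 0 lower; adjusted over the list alone, 6 and 0. Camera called none of the 3 lists (adjusted p = 0.971, 0.689 and 0.445; adjusted p = 0.985, 0.978 and 0.978 with an estimated correlation). Without at least 1 of replicates 2 and 3 of 6 months and 1, 2 and 3 of 36 months, the calls of timp4.2, fbn1, serpinh1b, lmod1b, kcnj8, lyve1a, sox7 and kdr ended (adjusted p up to 0.0715, 0.0645, 0.0882, 0.0627, 0.101, 0.0608, 0.0793 and 0.0935). For serpinh1b this also held without replicate 1 of 12 months or any replicate of 24 months.

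Some lists of immune genes lay higher at 36 than at 6 months by camera, with few genes passing alone and none of the lists called with an estimated correlation. The gelatinase mmp9 rose from 2.34 ± 1.96 to 12.1 ± 3.16 FPKM and was the 1 gene called of 38 macrophage and granulocyte markers. Adjusted over the list alone 0 were called by limma, and 8 higher and 0 lower had an unadjusted p under 0.05. The median was 0.62 on the log2 scale, and 0.38 to 1.14 without single libraries. The T cell gene themis rose from 0.765 ± 0.702 to 6.77 ± 2.96 FPKM, the 1 gene called of 22 lymphocyte markers over all genes and adjusted over the list alone. Of 31 interferon-stimulated genes 0 passed limma's test, over all genes or adjusted over the list alone, with a median of 0.47 (0.27 to 0.74 without single libraries) and 5 higher and 0 lower at an unadjusted p under 0.05. The interferon list did not rise steadily: its median was 0.27 at 12 against 6 months (camera adjusted p = 0.000953), -0.35 at 24 against 12 (0.00169), -0.08 at 24 against 6 (0.826) and 0.52 at 36 against 24 (0.0003). With an estimated correlation these had adjusted p = 0.995, 0.993, 0.983 and 0.891. The call at 12 against 6 months ended without replicate 2 or 3 of 6 months (adjusted p up to 0.103), and the median at 24 against 6 months ran from -0.34 to 0.24 without single libraries. The inflammatory transcription factor stat3 rose by 1.23 ± 0.14 on the log2 scale, a locus without a name overlapping it. Hepatocyte markers, which a heart sample should lack, had a median of -0.80 on the log2 scale (-0.23 without replicate 1 of 6 months, and -1.21 at the other end) with 0 of 39 past limma's test, over all genes or adjusted over the list alone, and 0 higher and 3 lower at an unadjusted p under 0.05. Camera called these 4 lists (macrophage adjusted p = 0.00074, lymphocyte 0.0196, interferon 0.00524 and hepatocyte 0.0196), and each had adjusted p = 0.978 with an estimated correlation. The macrophage and interferon calls ended without replicate 2 or 3 of 6 months (adjusted p up to 0.0648 and 0.0663), the lymphocyte call without these or replicate 1 or 2 of 36 months (up to 0.188), and the hepatocyte call without replicate 1 of 6 months (0.585) or replicate 2 of 36 months (0.0574). Camera did not call cytokines (adjusted p = 0.0741), antigen presentation (0.0634) or complement (0.656). The call of mmp9 ended without any replicate of 12 or 36 months, replicates 2 or 3 of 6 months or replicate 2 of 24 months (adjusted p up to 0.149), and that of themis without replicates 1 or 2 of 36 months (up to 0.0533).

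Of 43 heat shock and chaperone genes, 6 were lower and 1 higher at 36 than at 6 months; adjusted over the list alone, 7 and 1. The cochaperone genes ahsa1a, chordc1a and fkbp4 fell by 1.52 ± 0.33, 1.04 ± 0.23 and 0.56 ± 0.13 on the log2 scale, while cct4, a subunit of the chaperonin TRiC, rose from 217 ± 16.2 to 326 ± 3.15 FPKM. Of 43 proteasome subunit genes, 1 was higher, psma1, from 111 ± 5.44 to 148 ± 6.99 FPKM, and 7 were higher adjusted over the list alone. Of 65 splicing factor genes, 6 were higher and 1 lower; adjusted over the list alone, 7 and 1. The spliceosome gene snrpb rose from 161 ± 19.3 to 308 ± 61.1 FPKM, with 289 ± 29.9 already at 24 months. Of 47 senescence and p53 target genes, 2 were higher and 2 lower, over all genes and adjusted over the list alone. The sestrin gene sesn3 fell from 29.1 ± 3.67 to 12.3 ± 1.89 FPKM, btg2 fell as given above, and tp53inp1 and tp53i11b rose by 1.17 ± 0.28 and 0.88 ± 0.22 on the log2 scale. Camera called proteasome subunits (adjusted p = 5.22e-05) and splicing factors (adjusted p = 0.0457). It did not call chaperones (adjusted p = 0.0835) or senescence genes (adjusted p = 0.634). The chaperone list was called lower at 24 against 6 months (median -0.34 on the log2 scale, camera adjusted p = 7.96e-05; adjusted p = 0.634 with an estimated correlation) and at 24 against 12 months (camera adjusted p = 0.0214, and up to 0.065 without replicate 2 of 12 months or replicate 3 of 24 months; adjusted p = 0.893 with an estimated correlation). At 36 against 6 months all 4 had adjusted p = 0.978 with an estimated correlation, and the splicing call held in 7 of 12 fits that left out a library (adjusted p up to 0.235). Without at least 1 of replicates 2 and 3 of 6 months and 1, 2 and 3 of 36 months, ahsa1a, chordc1a, fkbp4, psma1, tp53inp1 and tp53i11b lost their call (adjusted p up to 0.0721, 0.0675, 0.0881, 0.089, 0.102 and 0.103).

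**Figure D4:**
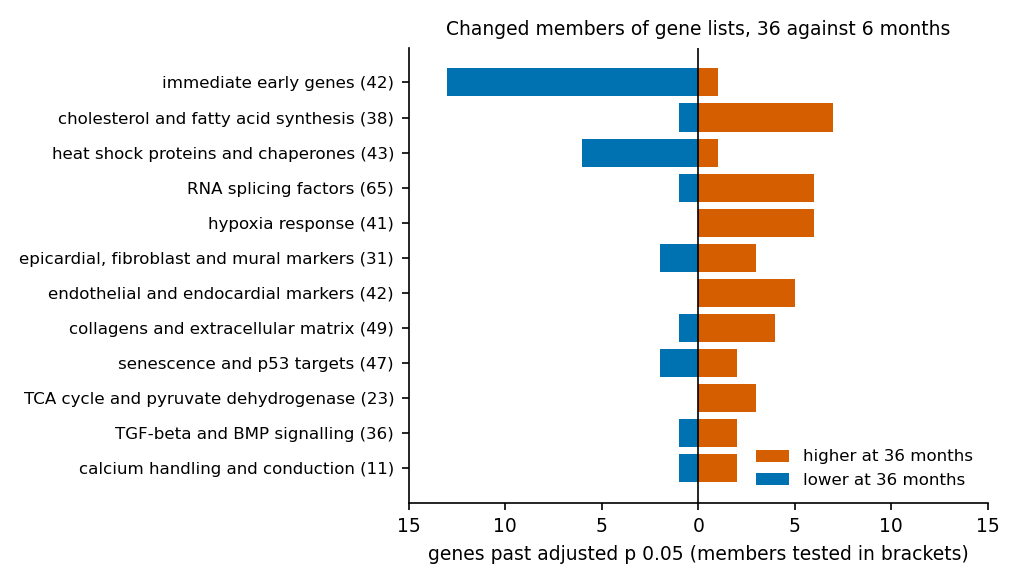
Members of gene lists past an adjusted p of 0.05 between 6 and 36 months, for lists with at least 3 such members. Bars to the right count genes higher and bars to the left genes lower at 36 months, with the members tested in brackets; immediate early genes had 13 lower and 1 higher of 42.

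Noncoding genes and loci without a name changed as well, at shares no higher than that of all genes tested. Between 6 and 36 months 5.5% of noncoding genes and 8.0% of loci without a name passed, against 8.2% of all genes tested. Of 362 noncoding genes tested, which leave out rRNA, snRNA, snoRNA and miRNA genes, 20 passed between 6 and 36 months, 7 higher and 13 lower. The antisense RNA CU459094.3 rose from 2.62 ± 0.646 to 17.6 ± 9.05 FPKM, and CT737162.2 and CR383676.1 rose by 1.54 ± 0.40 and 1.41 ± 0.31 on the log2 scale. The long intergenic RNA FQ790226.1 fell from 13.6 ± 5.96 to 0.85 ± 1.47 FPKM, and BX548073.3 and CR762497.1 fell by 2.73 ± 0.69 and 1.73 ± 0.43 on the log2 scale. Loci without a name overlap CR383676.1 and CR762497.1 on the same strand. Of 5730 loci without a name, 457 passed, 175 higher and 282 lower. Only FQ790226.1 among these 6 kept its call without each library. The others reached adjusted p = 0.0654, 0.11, 0.0783, 0.107 and 0.112 in the order named, each without at least replicate 3 of 36 months. The noncoding count was 35 without replicate 1 of 6 months, 8 without either other replicate of 6 months, and 12, 6 and 9 without replicates 1, 2 and 3 of 36 months.

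The comparisons with 24 months ask what had changed before the oldest age. Some circadian clock genes differed at 24 against 6 months. The clock repressors nr1d1, nr1d2b and ciarta fell from 67.1 ± 23.4 to 12.6 ± 3.51, 74.3 ± 7.3 to 36.2 ± 4.82 and 40.6 ± 11.51 to 11.3 ± 2.81 FPKM, and nr1d4b, of the same receptor family as nr1d1, rose from 1.12 ± 0.843 to 8.21 ± 3.63. The period gene per3 fell by 1.52 ± 0.18 on the log2 scale, overlapped by a locus without a name. Of 30 clock genes tested, 2 were higher and 4 lower. Adjusted over the list alone, 9 were higher and 7 lower. Camera, which tests for a single direction, did not call them (adjusted p = 0.724; adjusted p = 0.983 with an estimated correlation). The cell cycle inhibitor cdkn1a rose from 20.5 ± 4.93 at 6 to 51 ± 4.46 FPKM at 24 months and was 20.7 ± 5.65 at 36 months. The lysozyme gene lyz rose from 33.3 ± 37.3 to 821 ± 496, the somatostatin receptor gene sstr5 from 0.358 ± 0.275 to 7.36 ± 1.81 and rcan3, a regulator of calcineurin, from 14.3 ± 5.65 to 58.8 ± 12. The heat shock factor hsf2 fell from 18.9 ± 3.22 to 5.52 ± 0.78 FPKM and mat2ab, of methionine metabolism, from 8.76 ± 3.34 to 1.64 ± 0.361. The largest changes also held soul5l (log2 2.77 ± 0.50) and btg2 (log2 -2.65 ± 0.38), both overlapped by a locus without a name. In all, 115 genes passed, 69 higher and 46 lower. Genes higher were 60.0% of those called, and 76.9% with mitochondrial and haemoglobin genes removed or 75.7% with an equal sum per library.

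**Figure D5:**
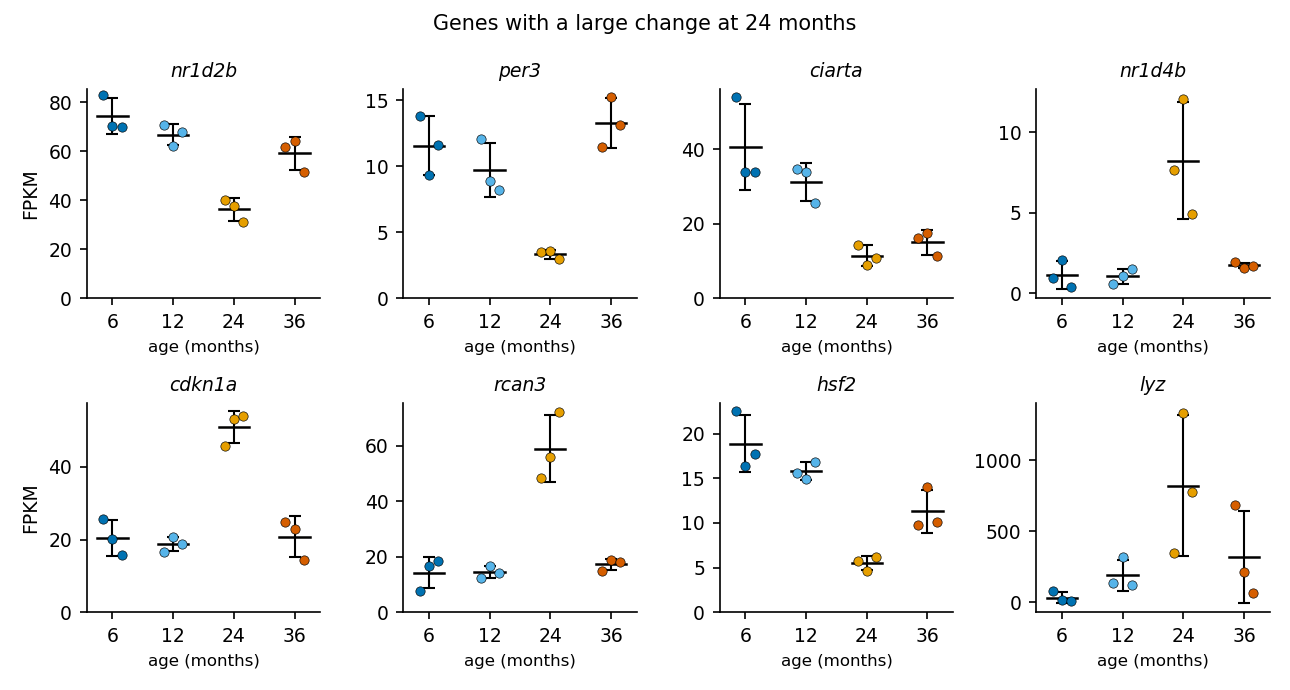
Levels of 8 genes with a large change at 24 months. Points are FPKM of single libraries by age in months, horizontal lines are means and bars are SD over 3 libraries; cdkn1a was at 51 ± 4.46 at 24 months and 20.5 ± 4.93, 18.7 ± 2.0 and 20.7 ± 5.65 at 6, 12 and 36 months. A locus without a name overlaps per3 on the same strand.

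The calls of the 24 against 6 month comparison leaned on single libraries. Over every alternative of the processing, 0 of the 10 genes named by rule and 0 of 10 list members kept their call. The calls of sstr5, nr1d1, hsf2, per3 and nr1d2b held without each of the 12 libraries. Those of lyz, soul5l, nr1d4b, rcan3, btg2, mat2ab, ciarta and cdkn1a ended without at least 1, replicate 2 of 24 months in each case (adjusted p up to 0.138, 0.138, 0.0805, 0.0521, 0.0677, 0.0803, 0.0616 and 0.114). Without replicate 3 of 6 months all but rcan3 and ciarta of these lost it too, and lyz and soul5l also lost it without replicate 1 or 2 of 12 months. The count was 320 without replicate 1 of 6 months, 58 and 34 without replicates 2 and 3, 55 and 68 without replicates 1 and 2 of 12 months, 26, 20 and 32 without replicates 1, 2 and 3 of 24 months, and 65 without replicate 2 of 36 months.

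Against 12 months, the 24-month hearts differed in several genes named above. The receptor gene sstr5 rose by 2.08 ± 0.27 on the log2 scale, nr1d4b by 2.12 ± 0.33, rcan3 by 1.95 ± 0.27 and cdkn1a by 1.40 ± 0.21, and ciarta fell by 1.40 ± 0.24. Genes that fell also included 3 others. The level of rbp2a, a retinoid-binding protein gene, went from 220.1 ± 63.8 to 35 ± 15.7 FPKM, the arginase gene arg2 from 313 ± 43.9 to 92.9 ± 23.05, and the carboxylate transporter gene slc5a8l from 23.12 ± 7.33 to 6.98 ± 2.05. The changes of soul5l (log2 2.68 ± 0.50), SNORA26 (log2 2.02 ± 0.37) and phactr3b (log2 -1.72 ± 0.33) are uncertain because loci without a name overlap them. Of 30 clock genes, 1 was higher and 3 lower; adjusted over the list alone, 7 and 9. Camera did not call them (adjusted p = 0.92; adjusted p = 0.993 with an estimated correlation). In all, 116 genes passed, 79 higher and 37 lower. With mitochondrial and haemoglobin genes removed rbp2a and phactr3b lost their call (adjusted p = 0.0568 and 0.0547). None of these named calls held without each library: replicates 1 and 2 of 12 months and 1 and 2 of 24 months ended every named call, with adjusted p up to 0.176 (phactr3b), and for some genes so did every other library except replicate 1 of 6 months. The count was 246 without replicate 1 of 6 months, 1, 3 and 196 without replicates 1, 2 and 3 of 12 months, 3, 4 and 28 without replicates 1, 2 and 3 of 24 months, and 71 without replicate 2 of 36 months.

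From 24 to 36 months, foxo1a rose by 2.09 ± 0.25 on the log2 scale (adjusted p = 0.00492) and zbtb16b by 1.73 ± 0.35, while atf3 fell by 2.01 ± 0.24 (adjusted p = 0.00492). The calcium channel subunit gene cacng8b fell from 6.17 ± 0.166 to 1.19 ± 0.318 FPKM, the integrin gene itga10 from 4.82 ± 2.4 to 0.21 ± 0.139, the microtubule gene map1aa from 4.97 ± 2.05 to 0.748 ± 0.275 and the sterol hydroxylase gene CYP27A1 (1 of many) from 7.61 ± 2.45 to 1.65 ± 0.895. The 24-month change of several genes turned back: cdkn1a fell by 1.29 ± 0.21 and rcan3 by 1.70 ± 0.27, and per3 rose by 1.71 ± 0.18. The sterol genes insig1 and lss rose by 1.11 ± 0.19 and 1.14 ± 0.20. Of 38 genes of cholesterol and fatty acid synthesis, 2 were higher and 0 lower; adjusted over the list alone, 4 and 1 (camera adjusted p = 0.00685, and 0.0539 without replicate 3 of 36 months; adjusted p = 0.891 with an estimated correlation). The urea cycle gene ASS1 (log2 2.43 ± 0.45) and igl3v3 (log2 3.30 ± 0.41) are overlapped by loci without a name, and a U1 gene of a multi-copy family, listed at 0 in every 24-month library, was at 4.02 ± 1.26 FPKM at 36 months. In all, 181 genes passed, 78 higher and 103 lower. The balance depends on the processing: it was 107 higher and 68 lower with no filter, and 32 and 83 with a pseudocount of 0.1. The calls of foxo1a, atf3, cacng8b, igl3v3 and per3 held without each library. Those of zbtb16b, itga10, map1aa, CYP27A1 (1 of many), ASS1, U1, cdkn1a, rcan3, insig1 and lss ended without at least 1 library of 24 or 36 months (adjusted p up to 0.168 for zbtb16b). With mitochondrial and haemoglobin genes removed zbtb16b, CYP27A1 (1 of many) and insig1 lost their call (adjusted p = 0.0577, 0.0543 and 0.0532). The count was 399 without replicate 1 of 6 months, 107 and 109 without replicates 1 and 2 of 12 months, 37, 43 and 61 without replicates 1, 2 and 3 of 24 months, and 58, 39 and 46 without replicates 1, 2 and 3 of 36 months.

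Between 6 and 12 months few genes passed. The gene zpld1b fell from 5.96 ± 1.29 to 1.52 ± 0.133 FPKM and the leiomodin gene lmod1b from 22.4 ± 1.47 to 10.3 ± 1.25, with 19.6 ± 2.44 at 24 months. A locus without a name on chromosome 1, 52541859 to 52548288, minus strand, rose from 1.68 ± 0.458 to 7.98 ± 1.0 FPKM. It lies outside the rule for named genes and was singled out after its values were seen. These were the 3 genes past limma's test, all with adjusted p = 0.031. By limma, 1533 had an unadjusted p under 0.05. Immediate early genes had a median of -0.62 on the log2 scale, with 0 of 42 past limma's test over all genes, 0 higher and 19 lower at an unadjusted p under 0.05 and 12 lower adjusted over the list alone (camera adjusted p = 1.09e-09; adjusted p = 0.494 with an estimated correlation). The 3 calls ended without any replicate of 6 or 36 months, replicates 1 or 2 of 12 months, or replicate 1 of 24 months (adjusted p up to 0.187). By limma they also ended with mitochondrial and haemoglobin genes removed (adjusted p = 0.0752 for each) and with an equal sum per library (adjusted p = 0.0686 for each). The count was 30 without replicate 3 of 12 months.

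Across all ages, 1341 genes had a slope in age past the threshold, 689 up and 652 down, and 857 differed across the 4 ages by the F test. Among named genes the steepest upward slopes were those of ccl38a.4, igl3v3, zbtb16b, ASS1 and cst14b.2, and the steepest downward those of ppp1r27b, btg2, nr1d1, atp5j, a subunit of ATP synthase, and nr4a1. A slope does not mean a steady change: of the 1341 genes, 842 had age means that moved in a single direction over the 4 ages. The slope of zbtb16b was 0.10 ± 0.01 on the log2 scale per month (adjusted p = 0.00226) and that of nr1d1 -0.08 ± 0.01 (adjusted p = 0.00333). Differences that share no library were compared across genes, which are not independent replicates. The pair 24 minus 6 against 36 minus 12 months gave Pearson r = 0.239 over 16223 genes (jackknife SE 0.111), and 12 minus 6 against 36 minus 24 months r = 0.131 (SE 0.0673). Of the 10 trend genes named, igl3v3, ASS1, cst14b.2, ccl38a.4, ppp1r27b and atp5j lost their call without at least 1 library of 36 months (adjusted p up to 0.0736, 0.0708, 0.0642, 0.0579, 0.0669 and 0.0724). The trend count was 2125 without replicate 1 of 6 months, 759 and 680 without replicates 2 and 3, and 529, 560 and 604 without replicates 1, 2 and 3 of 36 months. The F test gave 1653 without replicate 1 of 6 months and 310 to 522 without any other replicate apart from replicate 3 of 12 months (1011).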

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

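The leaving out of loci without a name and the array weights were chosen after the results were seen; the other alternatives were planned. No difference of a named gene reversed its direction under any alternative, but the balance of higher and lower genes did, as given below. For genes named because their values did not overlap between 2 ages, leaving out a library could not have reversed it. Apart from single libraries, 75 counts stayed within 1.5 times their value, 37 fell below and 7 rose above. Among differences of named genes 1923 kept direction and call and 400 lost the call. The losses were uneven: the fit of only the 2 ages compared kept 51 calls and lost 111, and replicate number as a block kept 114 and lost 58. Beyond what is explained by fewer genes or libraries tested, or by the added fold requirement, the cause of these changes was not tested.

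With no filter, which adds genes near 0, the counts were 889 (36 against 6 months), 49 (24 against 6), 0 (12 against 6), 53 (24 against 12), 433 (F test) and 752 (trend). With replicate number as a block they were 885, 50, 0, 41 and 64 for 36 against 6, 24 against 6, 12 against 6, 24 against 12 and 36 against 24 months, 354 for the F test and 843 for the trend. A fit of only the 2 ages compared gave 278, 2 and 0 for 36, 24 and 12 against 6 months and 3 noncoding genes. A doubling or halving left 595 (36 against 6), 75 (24 against 6), 74 (24 against 12), 554 (F test), 489 (trend) and 12 noncoding genes. Array weights, which give replicate 1 of 6 months a weight of 0.318, gave 2038, 377, 18, 762 and 442 for the pairwise comparisons in the order of the block, 2227 for the F test and 37 noncoding genes.

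Without loci that lack a name and the genes they overlap, 813 (36 against 6), 90 (36 against 24), 537 (F test) and 871 (trend) genes passed, and without those loci alone 99 for 36 against 24 months. That comparison also gave 115 with a pseudocount of 0.1, 118 with a mean FPKM of at least 5, 114 without trend in eBayes and 64 by voom, and voom gave 13 noncoding genes. For 12 against 6 months a mean FPKM of at least 5 left 1 gene, and removing mitochondrial and haemoglobin genes, an equal sum and eBayes without trend left 0. The share of higher genes at 24 against 6 months, 60.0%, was 76.9% with mitochondrial and haemoglobin genes removed (80 higher, 24 lower) and 75.7% with an equal sum (78 and 25). The balance turned elsewhere. For 36 against 6 months, 641 higher and 697 lower became 491 and 398 with no filter, 475 and 462 with a mean FPKM of at least 5, 526 and 464 without loci that lack a name, and 429 and 384 without those loci and the genes they overlap. It also turned without 5 of the 12 libraries, replicates 2 and 3 of 6 months and all 3 of 36 months (262 and 217 without replicate 2 of 36 months). For 36 against 24 months, 78 and 103 became 107 and 68 with no filter (32 and 83 with a pseudocount of 0.1, not turned), and nearly level without replicate 1 of 24 months (19 and 18) or replicates 1 (30 and 28) or 2 (20 and 19) of 36 months. For 24 against 12 months, 79 and 37 became 88 and 108 without replicate 3 of 12 months, for 24 against 6 months 69 and 46 became 151 and 169 without replicate 1 of 6 months, and for noncoding genes 7 and 13 became 5 and 3 without replicate 3 of 6 months. For 12 against 6 months, 1 and 2 became 16 and 14 without replicate 3 of 12 months and 11 and 7 with array weights. The trend balance, 689 up and 652 down, became 641 and 665 with a pseudocount of 0.1, 1050 and 1075 without replicate 1 of 6 months and 620 and 631 without replicate 1 of 24 months. No rescaling moved the median of all genes by more than 0.0853 on the log2 scale. Median-ratio size factors moved it by at most 0.008, since the deposited values already follow such factors.

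Leaving out each library in turn, with the remaining libraries of that age assumed to vary like the other ages, gave 479 to 2088 genes (36 against 6 months), 20 to 320 (24 against 6), 0 to 30 (12 against 6), 1 to 246 (24 against 12), 37 to 399 (36 against 24), 310 to 1653 (F test), 529 to 2125 (trend) and 6 to 35 noncoding genes. The highest of most ranges came without replicate 1 of 6 months, and that of 12 against 6 months without replicate 3 of 12 months. Without 36-month replicate 2, which gave the lowest 36 against 6 month count, 449 of the 1338 genes kept their call. All 1338 kept their sign without any 1 library. For 1334 of them this was fixed in advance, since their values did not overlap between the 2 ages. Of the genes named by rule, 14 of 26 (36 against 6, noncoding included), 3 of 10 (24 against 6), 0 of 2 (12 against 6), 0 of 10 (24 against 12), 4 of 10 (36 against 24) and 4 of 10 (trend) kept their call without each library. In each of 4 rescalings, 26 of 26, 10 of 10, 0 of 2, 8 of 10, 8 of 10 and 10 of 10 of these kept it, in the same order. Of members of lists, 51 of 68 (36 against 6), 8 of 10 (24 against 6), 8 of 10 (24 against 12) and 8 of 15 (36 against 24) did. At 36 against 6 months, camera with the preset correlation called immediate early genes, proteasome subunits and cholesterol and fatty acid synthesis without each of the 12 libraries, but all 3 had adjusted p = 0.978 with an estimated correlation. Depth limits low genes: with 7333060 to 11145869 reads in genes, 1 read of a 1 kilobase gene is 0.0878 to 0.136 FPKM.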

Other observations

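Apart from the splits of the libraries and the tests of genes and lists, the tests in this part were chosen after the results were seen.

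Some gene groups not described above also held changed genes at 36 against 6 months. The oxygen-responsive gene ankrd37 rose from 4.22 ± 2.71 to 15.3 ± 2.28 FPKM and the mitophagy receptor gene bnip3lb from 119 ± 13 to 179 ± 17.7; 6 of 41 hypoxia response genes were higher and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.978 with an estimated correlation). Camera no longer called that list without replicate 1 of 6 months or replicate 2 or 3 of 36 months (adjusted p up to 0.259). The call of ankrd37 ended without replicate 2 of 36 months (adjusted p = 0.0517) and that of bnip3lb without replicate 3 of 6 months or replicates 1 or 3 of 36 months (adjusted p up to 0.0711). The regulator of the antioxidant response keap1a rose from 15.7 ± 0.785 to 31.7 ± 0.945 FPKM (log2 0.97 ± 0.12, adjusted p = 0.00251), the 1 gene called of 58 antioxidant genes over all genes and adjusted over the list alone (camera adjusted p = 0.634; adjusted p = 0.978 with an estimated correlation). The stress pseudokinase gene trib3 fell from 142 ± 15 to 52.7 ± 16.3 FPKM (log2 -1.44 ± 0.19, adjusted p = 0.00387) and, with cdnf, was among 2 lower of 41 endoplasmic reticulum stress genes, the count also adjusted over the list alone (camera adjusted p = 0.95; adjusted p = 0.985 with an estimated correlation). Both keap1a and trib3 kept their call without each of the 12 libraries, and cdnf, overlapped by a locus without a name, lost it without replicates 2 or 3 of 6 months, among others (adjusted p up to 0.116).

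Cell cycle genes lay higher as a list at 24 months, and also at 36 against 6 months. Their median was 0.44 on the log2 scale at 24 against 6 months (0.20 to 0.62 without single libraries) and 0.39 against 12 months (0.18 to 0.53), with 0 of 65 genes past limma's test in both, over all genes or adjusted over the list alone; 14 higher and 0 lower had an unadjusted p under 0.05 against 6 months, and 10 higher and 0 lower against 12. Camera gave adjusted p = 1.57e-08 and 1.14e-06, and adjusted p = 0.983 and 0.993 with an estimated correlation. The call against 12 months ended without replicate 3 of 24 months (adjusted p = 0.0923). At 36 against 6 months the median was 0.30 (0.19 to 0.47 without single libraries) and 1 of 65 genes passed limma's test (camera adjusted p = 0.00109; adjusted p = 0.978 with an estimated correlation). That call ended without replicate 3 of 6 months (adjusted p = 0.084) or replicate 1 of 36 months (adjusted p = 0.0641), and 36 against 24 months was not called (adjusted p = 0.264). Thrombocyte markers had a median of 0.48 for 24 against 12 months (fry adjusted p = 0.033; camera adjusted p = 0.0116; adjusted p = 0.348 with an estimated correlation), with 0 of 10 past limma's test over all genes, 1 adjusted over the list alone and 3 higher and 0 lower at an unadjusted p under 0.05. That camera call ended without replicate 2 of 12 months (adjusted p = 0.065). Macrophage and granulocyte markers also lay higher at 24 months, with a median of 0.27 against 6 months (camera adjusted p = 0.012) and 0.34 against 12 months (camera adjusted p = 0.0298). These calls held in 8 and 9 of 12 fits that left out a library, and not with an estimated correlation.

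The real grouping was set against other splits of the same libraries. Splits of 3 against 3 number 10, too few for a share under 0.05. The real split gave 1338 genes for 36 against 6 months and the highest other 2, with 115 and 2 for 24 against 6, 116 and 1 for 24 against 12, 181 and 1 for 36 against 24, and 20 and 0 for noncoding genes; in each, 1 of 10 splits, the real one, gave as many. For 12 against 6 months the real split gave 3 genes and the highest other 7, and 2 of 10 gave as many. Chance is unlikely for the F test, with 857 genes against at most 113, and for the trend, with 1341 against at most 3. In both, 1 of 100 assignments, the real one, gave as many. These counts do not separate age from anything else that differed between the groups of libraries. Lists called by camera with the preset correlation numbered 11 (36 against 6), 6 (24 against 6), 4 (12 against 6), 5 (24 against 12) and 11 (36 against 24), and 7, 9, 10, 10 and 7 of 10 splits gave as many, with highest others of 22, 19, 17, 12 and 15. These list calls are no more than other splits of the libraries give, and the cause was not tested.

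Several genes of known high expression in the heart are listed near 0, below 0.1 FPKM, where a locus without a name overlaps them. Among ribosomal protein, proteasome and oxidative phosphorylation genes, 29 of 72 overlapped on the same strand (40.3%, 95% exact interval 28.9% to 52.5%) were near 0, against 0 of 153 not overlapped on it (Fisher exact p = 4.09e-17, two-sided). Low expression in the heart is argued against, since the upper limit of the 95% exact interval of the share near 0 among genes not overlapped is 2.38%. A candidate explanation is that their reads were counted for the locus without a name or dropped because of it. Such loci overlap 7686 protein-coding genes (29.9%), so the levels of those genes may be too low.

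Clock genes set the 24-month hearts apart. The mean of 4 activators minus the mean of 9 repressors and outputs lay at -0.185 to 0.287 at 24 months and at -2.65 to -0.523 in the other 9 libraries. The difference was 1.31 on the log2 scale, and the genes and the age were picked after this was seen. At least 99.53% of the difference of the activators alone (1.09) was kept under each of 4 rescalings, so it does not depend on which of these scalings is used. The rescalings could hardly have removed it, since they moved the median of all genes by at most 0.0853 on the log2 scale. They therefore do not decide about library scaling in general. On this score the highest 36-month library lay at -0.523, below all of 24 months. That cannot decide about a steady change with age, because the genes and the age were picked for standing apart at 24 months. A collection at another time of day cannot be told apart from age here: the labels give no times, and the activators lay higher at 24 months (3.25 to 3.58 against 1.26 to 2.66) while the repressors overlapped (3.30 to 3.44 against 3.18 to 3.91, difference -0.217). A change that is largest at 24 months stays open, untested.

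Immediate early genes were lower at 36 months, with a list mean of 4.94 to 5.06 on the log2 scale against 5.73 to 5.96 at 6 months. The fall was not progressive: 12 months lay at 4.99 to 5.36 and 24 months at 5.22 to 5.64. Camera also called the list lower at 24 against 6 months (adjusted p = 0.000654; adjusted p = 0.983 with an estimated correlation). A single library is argued against, since the median difference stayed between -0.75 and -0.54 without each of the 12 libraries and was -0.62 without replicate 1 of 6 months. At least 93.75% of the difference was kept under each of 4 rescalings, so it does not depend on which of these scalings is used. As these moved the median of all genes by at most 0.0853 on the log2 scale, they do not decide about library scaling in general. Handling that varied between hearts cannot be told apart from age for these genes: their deviations from the age means had a mean pairwise correlation of 0.120, between the median (0.0551) and the 95th percentile (0.121) of 1000 random lists. A difference in handling between ages could also give this pattern and the labels do not describe it, so a biological effect of age stays open beside it.

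Some loci were on in every library of an age (at least 20 reads) and off in every library of another (at most 2 reads): 40 between 24 and 36 months (20 each way, 27 without a name), 25 between 12 and 36, 23 between 6 and 36, 8 between 6 and 12, 7 between 6 and 24 and 7 between 12 and 24.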
